A study of Mus musculus with 8 samples.

How the data were processed

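Polyadenylated RNA was sequenced from mouse macrophages in 3 cell types, each unstimulated (0 h) and after 3 h with lipopolysaccharide (LPS). Groups and replicates were taken from the sample labels. Bone marrow-derived macrophages (BMDM) had 2 libraries per state, and the cell type labelled hMPDM and the line RAW 264.7 (RAW) had 1 library per state, which makes 6 groups of 8 libraries. Per the series description, RNA was extracted with TRIzol and libraries were made with a KAPA stranded kit. The dose of LPS and the meaning of the abbreviation hMPDM are not given in the sources used here.

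The deposited table holds raw read counts per gene, with no normalization, and its header has the layout of featureCounts. The submitters' processing notes name cutadapt, STAR, SAMtools, bedtools and featureCounts, with no version, and the mm10 genome build. The table has 43346 genes and 10 value columns. A column was used where its name matched a single sample, which gave 8 columns, and the other 2 were not used. Gene identifiers were matched to symbols with a reference list of gene names, and to gene types and spans with GENCODE release M21. Of the identifiers, 42462 matched a symbol and 884 did not, and 20 shared a symbol with a more deeply counted identifier. The span was the same in the deposited data and in GENCODE for 33497 genes. Coordinates are those of the table (mm10, counted from 1).

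Library totals ranged from 3116434 to 19307312 counts. A count of 0 allows a level of up to 3 counts, which is 0.155 CPM (counts scaled to library size) in the deepest library and 0.963 CPM in the shallowest. Intervals of count ratios (95%, exact) and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

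Counts were analysed in edgeR 4.0.16 under R 4.3.3, with genes kept by filterByExpr and libraries scaled by TMM, which left 12461 genes. A quasi-likelihood fit with 1 coefficient per group used all 8 libraries and had 2 residual degrees of freedom, both from the BMDM pairs. It tested the LPS response of BMDM, hMPDM and RAW each against BMDM at rest, and the difference of each LPS response from that of BMDM. The single hMPDM and RAW libraries were assumed to vary as the BMDM pairs do. A further fit with cell type and LPS as terms tested a single LPS response over the 3 cell types, called common here, with 4 residual degrees of freedom. BMDM, with the most libraries, weighs most in it. Adjusted p-values are Benjamini-Hochberg values and were called at 0.05. An SE beside a log2 value is the size of that value divided by the square root of the quasi-likelihood F statistic. It is not a standard error taken from replicates. For large folds with few counts in a group it can fall below counting error alone. Where a group of a simple comparison had 0 counts, the fold is given as a bound against 3 counts over that group, and where it had 1 to 3 counts, as a ratio with its counting interval. Levels are TMM-scaled CPM. Genes said to change by more than 2-fold in a tested comparison are those past a test against a fold change of 2 (adjusted p under 0.05). Fewer genes pass that test than are called with an estimate of at least 2-fold.

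The LPS responses of hMPDM and RAW and the difference between these cell types at rest set 1 library against 1 library. They have no test and no p-value. A size rule counted genes with a log2 ratio (prior count 2) of at least 2 in size, that is 4-fold, and at least 5 CPM in the higher library. The same rule applied to BMDM replicate 1 against replicate 2 of 1 state gave the background. Responses were also correlated across genes, by Pearson and Spearman, with no p-value because genes are not replicates.

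The lists tested cover 25 gene groups: inflammatory cytokines and chemokines, NF-kB regulators, interferon-stimulated genes, immediate early genes, nitric oxide and oxidative defence, TLR4 signalling, MHC class II presentation, macrophage identity, alternative activation, complement with lipid handling, cell cycle, p53 targets, glycolysis, cholesterol biosynthesis, haematopoietic progenitors, markers of 8 other cell types (neutrophil, mast cell, B cell, T and NK cell, dendritic cell, osteoclast, fibroblast, erythroid), sex-linked genes, and stress genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), and again with an estimated correlation. The estimated form rests on the 2 residual degrees of freedom (4 in the common fit), so a small p-value is hard to reach. A call lost there does not show that a list failed to move. In comparisons of single libraries a list's median was placed among 10000 random lists matched on expression (seed 20). The lists, the tests, the size rule, most alternatives and the rule for naming genes were set before the data were examined. That rule takes the 8 largest rises and falls per tested comparison (6 in differences of responses and in untested comparisons) with at least 5 CPM, up to 4 members of each list described, and 20 genes named in every comparison, and it passes over predicted genes and pseudogenes. Some genes that it names are not reported here. Which lists to describe in each comparison was chosen after the list results were seen. Arg1, which is among the 20 genes, was not tested, with 0 to 3 counts per library.

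The alternatives were DESeq2 size factors (RLE), no filter, the DESeq2 1.42.0 Wald test, a replicate block, leaving out each library or cell type, both states averaged, a test against a fold change of 2, prior counts of 0.5 and 8, other size rules and other gene sets for the correlations. Added after seeing the data were reads thinned to the shallowest library, a coefficient of variation set at 10%, and a BMDM share taken out of the hMPDM LPS library. The pipeline was tested on simulated data with 200 changed genes per comparison. Of the genes changed 2-fold, from 75% (the RAW difference of responses) to 99% (BMDM LPS response) were recovered, of those changed 4-fold, from 96% to 100%, with 3 to 14 false calls. Outside the common response, all simulated libraries were drawn with the spread fitted to the BMDM pairs. These rates therefore hold only if hMPDM and RAW vary as BMDM do. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.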

Results

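The transcriptomes of 3 kinds of mouse macrophage were compared at rest and 3 h after LPS, the cell wall component of Gram-negative bacteria that is sensed by TLR4. BMDM are grown from bone marrow, here in L929-conditioned medium, and had 2 unstimulated and 2 LPS libraries. RAW is a macrophage-like mouse tumour line and had 1 library per state, as did hMPDM. No replicate error can be given for hMPDM or RAW values. An SE beside a difference of these cell types from BMDM rests on the spread of the BMDM pairs. The labels do not say whether the BMDM replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

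BMDM libraries held 15671839 and 19307312 counts at rest and 7977638 and 15261114 after LPS. The hMPDM libraries held 15318338 at rest and 5510319 after LPS, and the RAW libraries 3116434 and 4078496. Between 13060 (RAW at rest) and 16209 (BMDM at rest, replicate 2) genes had a read. Ctsd, Ctsb or Gpnmb, 2 lysosomal proteases and a lysosomal glycoprotein, was the top gene of each library, with 1.45% to 2.26% of counts. BMDM replicates correlated at 0.997 (rest) and 0.994 (LPS) across genes on the log2 scale. They differed by more than counting error (chi-square per degree of freedom 1.63 and 1.70), and their fitted coefficient of variation was 2.27%. The first principal component (61.9% of variance) set RAW apart from BMDM and hMPDM, and the second (25.1%) separated LPS from rest. At rest, hMPDM correlated with BMDM at 0.972 and RAW with BMDM at 0.849 to 0.850.

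The response of BMDM to LPS was a large rise of cytokine, chemokine and interferon-stimulated genes with a fall of cell cycle genes. Il12b, which encodes an interleukin subunit made by activated macrophages (ENSMUSG00000004296.10, chromosome 11, 44400063 to 44414033, mm10), went from 0.426 ± 0.328 to 585 ± 33.1 CPM (SD, n = 2). Cxcl10, an interferon-induced chemokine (ENSMUSG00000034855.9, chromosome 5, 92346638 to 92348889, mm10), went from 6.89 ± 0.490 to 7213 ± 103 CPM (SD, n = 2). In all, 3945 genes rose and 3870 fell of the 12461 tested. Of these, 1253 rose and 1009 fell by an estimate of at least 2-fold, and 1030 and 525 passed the test against a fold change of 2. Among the largest rises were Ccl5 (log2 9.80), Il6 (9.26), the acute phase gene Saa3 (9.13), the nitric oxide synthase Nos2 (9.05) and the neutrophil chemokine Cxcl1 (9.05). Few resting counts make the size of these folds imprecise: Il6 had 3 and 3, Cxcl1 1 and 4, and Nos2 8 and 9 in the BMDM libraries. Ifi208 was not counted at rest and reached 20.3 ± 0.553 CPM, at least 252-fold higher. Its sequence is close to that of other Ifi200 family genes, so reads shared between them are not excluded.

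The inflammatory list had 27 tested genes, of which 26 rose and 1, Osm, fell (log2 -0.31), with the same numbers adjusted over the list alone. Its median was 5.11 (4.68 with genes at 0 set to their bound). Tnf rose by 5.84 (SE 0.0460) and Il1b by 8.28, and Il10, an anti-inflammatory cytokine, rose by 2.89 to 4.06 CPM. The list moved upward as a set (camera adjusted p = 2.34e-16; adjusted p = 0.390 with an estimated correlation). All 43 tested interferon-stimulated genes rose, also adjusted over the list alone (median 5.11; camera adjusted p = 2.60e-28; adjusted p = 0.390 with an estimated correlation). Examples are Ifit1 (log2 9.02), Ifi205 (8.80) and the antiviral gene Rsad2 (8.66, SE 0.0590; ENSMUSG00000020641.11, chromosome 12, 26442753 to 26456452, mm10). Ifnb1, which encodes interferon beta, was not counted at rest and stood at 3.02 ± 0.424 CPM after LPS, at least 38.8-fold higher.

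Of 26 genes for NF-kB subunits and feedback regulators, 25 rose and 1, Trib1, fell (log2 -1.35), with the same numbers adjusted over the list alone and a median of 2.86. Socs3 (7.28), Traf1 (from 3.59 to 229 CPM), Socs1 (5.49) and Nfkbiz (5.32) rose most, and the inhibitors Nfkbia and Tnfaip3 rose by 4.16 and 4.27 (camera adjusted p = 1.46e-14; adjusted p = 0.390 with an estimated correlation). In the nitric oxide, prostaglandin and oxidative defence list 21 of 23 rose and 0 fell, also adjusted over the list alone (median 2.23). Acod1, which makes itaconate, rose by 7.73, the prostaglandin synthase gene Ptgs2 by 6.08 and Marcksl1 by 4.78 (camera adjusted p = 3.33e-12; adjusted p = 0.390 with an estimated correlation). Of 16 MHC class II and costimulation genes 12 rose and 0 fell, also adjusted over the list alone (median 0.69), with Cd40 at 7.01, Icosl at 3.85, Cd83 at 3.19 and the class II transactivator Ciita at 2.90 (camera adjusted p = 6.04e-05; adjusted p = 0.390 with an estimated correlation).

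Of 43 cell cycle genes 40 fell and 0 rose (42 fell adjusted over the list alone), with a median of -0.66. Cdc6, a loader of the replicative helicase (ENSMUSG00000017499.11, chromosome 11, 98907801 to 98923940, mm10), fell from 22.3 ± 1.12 to 2.67 ± 0.359 CPM (log2 -3.02, SE 0.149). Ccne2 (-1.87), Cdt1 (-1.43), Kif23 (-1.34) and the proliferation marker Mki67 (-0.51) also fell (camera adjusted p = 9.21e-14; adjusted p = 0.453 with an estimated correlation). Among the genes that fell were Sox4 (log2 -5.16, with 1 and 4 counts after LPS), Epha2 (-4.25), the chemokine receptor Cxcr4 (-4.05), Gpr183 (-3.65), Rasd2 (-3.60), Tfap4 (-3.60), Thbd (-3.48) and Cdca7 (-3.37). In the glycolysis list 14 of 18 rose and 1, Pdk1, fell (log2 -0.15), the same adjusted over the list alone. Its median was 0.43, with the hexokinase gene Hk2 at 1.60, the glucose transporter gene Slc2a1 at 1.31, and Slc16a3 and Hif1a at 1.04 each (camera adjusted p = 0.000288; adjusted p = 0.480 with an estimated correlation). Scaled by library size little of this median is left, and the summed level of the list was 4985 and 4914 CPM at rest and 4811 and 4973 CPM after LPS.

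Cd14, the LPS co-receptor, rose by 2.61 (SE 0.0360), Tlr4 fell by 0.48, the macrophage marker Adgre1 rose by 0.99 and Csf1r, the receptor for the growth factor CSF1, rose by 0.21. Hoxb4 did not pass (log2 0.19, adjusted p = 0.375). Scaling by library size in place of TMM would shift every BMDM value by -0.37, which turns the direction of changes as small as that of Csf1r. The call for Csf1r ended with the coefficient of variation set at 10%.

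**Figure D1:**
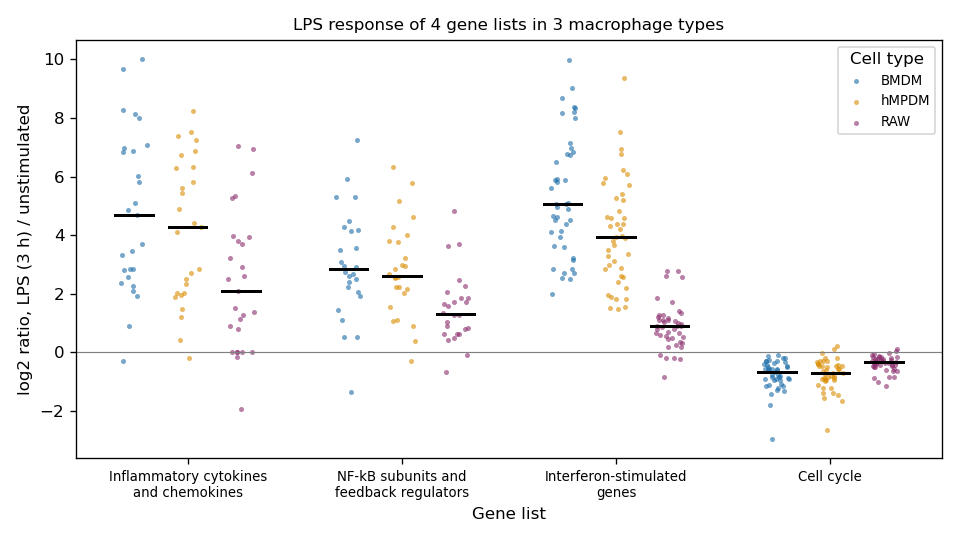
Log2 ratio of LPS to unstimulated CPM (prior count 2) for each tested gene of 4 lists in BMDM, hMPDM and RAW, with a bar at each median. The interferon-stimulated list has medians of 5.1, 3.92 and 0.89 in that order, and the cell cycle medians lie below 0 (-0.66, -0.71 and -0.34).

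Across cell types, the common LPS response followed the same gene groups. BMDM entered this fit with 2 libraries per state and hMPDM and RAW with 1 each, so the BMDM response weighs most. A common value can thus lie far from that of RAW, where the untested log2 ratios were 2.08 for Ccl5 and 2.77 for Cxcl10. With cell type in the model, 3110 genes rose and 3011 fell, of which 585 and 154 passed the test against a fold change of 2. Tnf rose by 5.34 (SE 0.360), Cxcl10 by 8.82 (SE 1.45), Ccl5 by 8.86 (SE 1.01), Ptgs2 by 5.81 (SE 0.175), Nfkbia by 3.58 (SE 0.367) and Cd14 by 2.37 (SE 0.276). Of the 27 inflammatory genes 26 rose and 0 fell, also adjusted over the list alone (median 4.88; camera adjusted p = 1.20e-16; adjusted p = 0.327 with an estimated correlation). All 43 interferon-stimulated genes rose, also adjusted over the list alone (median 4.21; camera adjusted p = 1.04e-14; adjusted p = 0.373 with an estimated correlation), with Ifit1 at 7.45 (SE 1.08). Of 26 NF-kB genes 25 rose and 1, Trib1, fell, also adjusted over the list alone (median 2.56; camera adjusted p = 5.73e-15; adjusted p = 0.327 with an estimated correlation). Of 43 cell cycle genes 39 fell and 0 rose, also adjusted over the list alone (median -0.61; camera adjusted p = 9.05e-14; adjusted p = 0.327 with an estimated correlation), among them Cdc6 (-2.32), Ccne2 (-1.56), Uhrf1 (-1.18) and Chek1 (-1.14). Genes that fell include Cxcr4 (-3.04), Id1 (-2.65), an inhibitor of differentiation factors, and Ccsap (-2.62). Csf1r (log2 0.13, adjusted p = 0.114) and Hoxb4 (0.17, adjusted p = 0.277) did not pass. Il12b (9.78) and Il6 (8.95) rose in this comparison, while in RAW Il12b had 2 counts at rest and 0 after LPS, and Il6 was not counted in either state. Of the interferon-stimulated genes, 5 were lower after LPS in the RAW libraries, which was not tested (log2 ratios of -0.85 for Iigp1, -0.24 for Cxcl11, -0.21 for Isg20, -0.19 for Gbp3 and -0.10 for Oasl2).

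In hMPDM, set against its own unstimulated library, most of the genes that were higher after LPS were also those of the BMDM response. By the size rule 439 genes were at least 4-fold higher after LPS and 113 lower. Between BMDM replicates 1 gene passed in either direction at rest and 0 after LPS, in libraries deeper than the hMPDM LPS library. Of the 439 and 113 genes, 375 and 52 passed the same rule in the same direction in BMDM, where 472 and 95 passed. Cxcl10 reached 5304 CPM from 7.93 (log2 ratio 9.35), Ccl5 713 CPM (8.25), Nos2 156 CPM (8.01) and the activation marker Cd69 1078 CPM (7.72). Il1b was 7.37 higher, Il6 7.52, Tnf 5.61 and Cd40 6.60. The rule was passed upward by 20 of 27 inflammatory genes (median 4.27), 20 of 26 NF-kB genes (median 2.61, Traf1 at 6.33) and 35 of 43 interferon-stimulated genes (median 3.92, Cmpk2 at 6.78). Each of these medians lay above all matched random lists (percentile 100). Of 43 cell cycle genes 1, Cdc6 (-2.65), passed, and the list median of -0.71 lay below all random lists (percentile 0). Lower after LPS were Fam78a (-3.42), Id1 (-3.29), Lpar5 (-3.26) and the myeloid transcription factor gene Cebpa (-2.87). Sox4 had 1 count after LPS, a ratio of 55.1 (9.78 to 2187).

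The hMPDM LPS library held reads of genes that were near absent in unstimulated hMPDM. For 16 genes, chosen after the values were seen for at least 5 CPM in BMDM in both states and at most 5% of the BMDM level in unstimulated hMPDM, the pooled level was 1.35% of that in BMDM at rest and 10.8% of that in BMDM after LPS. Tceal8, for example, stood at 0.541 CPM in hMPDM at rest and 5.67 CPM after LPS, and at 44.4 and 37.3 CPM in BMDM. The 256 genes chosen alike for RAW stood at 1.99% and 1.78%.

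In RAW fewer genes passed the same rule, among them inflammatory genes such as Il1b, Cxcl2 and Tnf. After LPS 78 genes were at least 4-fold higher and 1, Slc25a35, was lower (-2.05), and 60 of the 78 also passed upward in BMDM. Il1b had 3 counts at rest and 118 CPM after LPS, a ratio of 150.2 (51.1 to 731). Csf3, a granulocyte growth factor (ENSMUSG00000038067.2, chromosome 11, 98701263 to 98703629, mm10), was not counted at rest and reached 24.4 CPM, at least 31.1-fold higher. Cxcl2 (6.11), Ptgs2 (5.88), Traf1 (4.83), Acod1 (4.36), Tnf (3.93) and Socs3 (3.70) were also higher. Lif had a ratio of 47.7 (16.1 to 234) and Ccl22 was at least 9.27-fold higher. The rule was passed by 14 of 27 inflammatory genes (median 2.08), 6 of 26 NF-kB genes (median 1.32) and 4 of 43 interferon-stimulated genes (median 0.89, with Ifit1 at 2.78 and Isg15 at 2.61), and each median lay above all matched random lists (percentile 100). No cell cycle gene passed (0 of 43), and that list's median of -0.34 lay below all random lists (percentile 0). The absence of Il6 and Il12b reads after LPS does not exclude low levels at this depth. With a minimum of 1 CPM in place of 5, 165 genes passed in RAW.

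**Figure D2:**
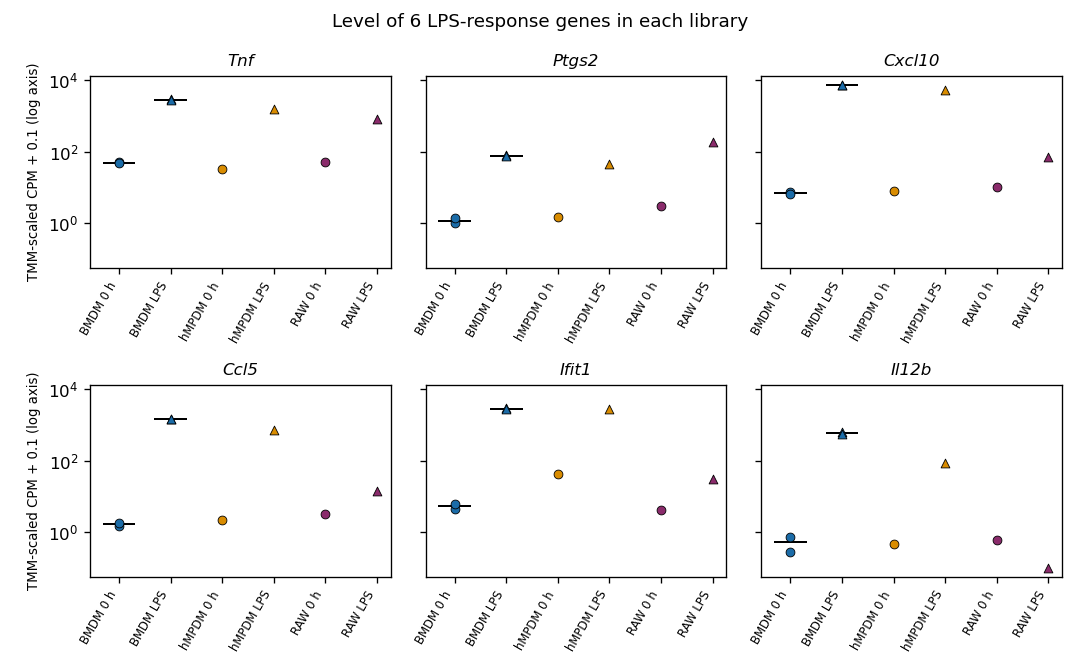
TMM-scaled CPM plus 0.1 on a log axis for 6 genes in each of the 8 libraries, with circles at rest, triangles after LPS and bars at BMDM means. After LPS Ptgs2 is higher in RAW (180.2 CPM) than in BMDM (77.5 CPM), and Cxcl10 is lower (69.1 against 7213 CPM).

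Across the 12461 genes, the log2 response of hMPDM correlated with that of BMDM at 0.879 (Pearson) and 0.810 (Spearman). RAW correlated with BMDM at 0.420 by both measures and with hMPDM at 0.410 and 0.405. The responses of BMDM replicate 1 and replicate 2 correlated at 0.935 and 0.854. Of the 1030 genes that rose in BMDM by the test against a fold change of 2, 923 were at least 2-fold higher in hMPDM and 277 in RAW. In hMPDM and RAW the untested ratio alone was counted. Median log2 ratios were 2.20 (BMDM), 2.01 (hMPDM) and 0.47 (RAW). Of the 525 that fell in BMDM by that test, 424 were at least 2-fold lower in hMPDM and 99 in RAW by the untested ratio (medians -1.72, -1.55 and -0.43).

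The test of the difference between the hMPDM and BMDM responses found smaller folds of interferon-stimulated genes and of some NF-kB and inflammatory genes in hMPDM, and a higher response of a few lipid genes. In all 979 genes passed, 494 with a higher and 485 with a lower response, of which 8 and 23 by more than 2-fold. Of 43 interferon-stimulated genes 35 had a smaller fold (39 adjusted over the list alone) and 0 a larger fold, with a median difference of -1.07 (camera adjusted p = 3.15e-54; adjusted p = 0.439 with an estimated correlation). Ifit1 differed by -3.06 (SE 0.129), Oasl1 by -2.86, Usp18 by -2.84 and Ifit3 by -2.63. These genes started higher in hMPDM: Ifit1 stood at 42.6 CPM at rest and 2670.5 CPM after LPS, against 5.27 and 2793 CPM in BMDM. Of 26 NF-kB genes 11 had a smaller and 3 a larger fold (12 and 3 adjusted over the list alone; median -0.22; camera adjusted p = 0.00299), and of 27 inflammatory genes 6 and 3 (7 and 3 adjusted over the list alone; median -0.45; camera adjusted p = 0.0139), each with adjusted p = 0.439 with an estimated correlation. Cxcl10 (-0.65), Ccl5 (-1.44), Nfkbia (-0.38) and Tnfaip3 (-0.28) also rose less. Some calls ended in the LPS response hMPDM minus BMDM: Tnfaip3 with the DESeq2 test, with the replicate block and without either BMDM unstimulated library (adjusted p = 0.0903 without replicate 1 and 0.103 without replicate 2), and Cxcl10 without BMDM unstimulated replicate 2 (adjusted p = 0.0560). Tnf (log2 -0.22, adjusted p = 0.176), Il1b (-0.77, adjusted p = 0.211) and Ptgs2 (-1.04, adjusted p = 0.126) did not pass. Il12b reached 83.3 CPM in hMPDM and 585 CPM in BMDM (difference -2.65, adjusted p = 0.0751), and 10.8% of the BMDM level, the pooled share given above, would be most of the hMPDM value.

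Among 24 complement and lipid handling genes 6 had a larger response in hMPDM and 1 a smaller (10 and 1 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 1.90e-05; adjusted p = 0.439 with an estimated correlation). They were Lpl, the lipoprotein lipase gene (1.19; ENSMUSG00000015568.11, chromosome 8, 68880491 to 68907448, mm10), C3ar1 (0.78), the cholesterol exporter gene Abcg1 (0.71), Apoe (0.70), Ctsz (0.25) and Ctsl (0.23), and Abca1 (-0.29) was the smaller. Slc13a3 differed by 4.12 and Rasd2 by 3.97. Ifi208 (0.541 CPM at rest and 13.1 CPM after LPS in hMPDM, adjusted p = 0.000589) and Ifi213 (0.481 and 4.80 CPM, adjusted p = 0.00547) rose less in hMPDM than in BMDM. Lipo3 (8 counts after LPS and 0 at rest in hMPDM, adjusted p = 0.00472), Sema3c (5 and 0 counts, adjusted p = 0.0256), Ube2e2 (5 and 0 counts, adjusted p = 0.0458) and Sel1l3 (12 and 3 counts, adjusted p = 0.000716) belong to the 16 genes near absent in unstimulated hMPDM. With the 10.8% share of the BMDM LPS level taken out of the hMPDM LPS library, Ube2e2 and Sel1l3 turned direction and the calls for Lipo3, Sema3c and Apoe ended, and that for Apoe also ended with the DESeq2 test. With reads thinned to the shallowest library 178 genes passed, and of the 22 named calls those for Ifit1, Oasl1, Usp18, Ifit3, Lpl and C3ar1 were kept. With the coefficient of variation set at 10% there were 123, and the calls for Cxcl10, Nfkbia, Tnfaip3, Cd14, Adgre1, C3ar1, Abcg1, Apoe, Sema3c and Ube2e2 ended.

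In RAW, interferon-stimulated and NF-kB genes rose less than in BMDM, and cell cycle genes fell less. In all 2832 genes passed, 1246 with a higher and 1586 with a lower response, of which 111 and 367 by more than 2-fold. Of 43 interferon-stimulated genes 41 rose less, also adjusted over the list alone, and 0 rose more, with a median difference of -4.23 (camera adjusted p = 1.81e-29; adjusted p = 0.287 with an estimated correlation). Rsad2 differed by -7.39 (SE 0.386), Cmpk2 by -7.26, Cxcl10 by -7.24, Mx1 by -7.14, Ifit1 by -6.20 and Ccl5 by -7.65. Ifnb1 had 1 count in RAW after LPS, and its difference did not pass. Of 26 NF-kB genes 20 rose less and 1, Trib1, had the higher response (1.98), the same adjusted over the list alone. Their median was -1.45 (camera adjusted p = 2.34e-12; adjusted p = 0.287 with an estimated correlation), with Socs3 at -3.53, Nfkbie at -2.91, Tnip3 at -2.79, Nfkbia at -2.10 and Tnfaip3, which reached 122 CPM in RAW and 889 CPM in BMDM. Tnf differed by -1.90 (SE 0.138), while Il1b (-1.07, adjusted p = 0.494) and Ptgs2 (-0.12, adjusted p = 0.943) did not pass.

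Cell cycle genes fell less in RAW, with 24 of 43 higher and 1, Ccne1 (-0.71), lower (26 and 1 adjusted over the list alone). Their median was 0.36 (camera adjusted p = 7.17e-09; adjusted p = 0.411 with an estimated correlation), with Cdc6 at 1.86, Ccne2 at 1.01, Kif20a at 0.96 and Kif23 at 0.95. The proto-oncogene Myc (ENSMUSG00000022346.10, chromosome 15, 61985341 to 61990374, mm10) went from 1.83 CPM (7 counts) to 15.8 CPM in RAW and from 50.1 ± 2.91 to 8.71 ± 0.989 CPM in BMDM (SD, n = 2). Cd14 (-1.40), Adgre1 (-0.46) and Csf1r (-0.21) responded less, and scaling by library size, a shift of 0.27 here, turns the direction for Csf1r. Genes with 0 to 3 counts in a RAW library were Il12b (585 CPM in BMDM after LPS and 0 in RAW, adjusted p = 0.000335), Slco3a1 (70.0 and 0 CPM, adjusted p = 0.00655), Cacnb3 (16.1 and 0 CPM, adjusted p = 0.0282), Plagl1 (14.8 and 0 CPM, adjusted p = 0.00899), Gem (7.75 and 0 CPM, adjusted p = 0.0107) and Socs1 (42.1 and 0.428 CPM, adjusted p = 0.0131). Nos2 stood at 2.78 CPM in RAW after LPS and also rose less (adjusted p = 0.00759). The response was higher in RAW than in BMDM for 4 other genes with few counts. After LPS in RAW, Lcn2 stood at 5.56 CPM (adjusted p = 0.0469), Kcna3 at 7 counts (adjusted p = 0.0490), Bcl6b at 7.28 CPM (adjusted p = 0.00222) and Ceacam19 at 16.9 CPM (adjusted p = 0.0320). The calls for Kcna3, Lcn2, Ceacam19 and Csf1r each ended when 1 BMDM library was left out, that for Ccne2 with the DESeq2 test, and those for Bcl6b, Cacnb3 and Socs1 with thinned reads. Kcna3 and Lcn2 also lost their calls with no filter. The total fell to 1374 with the DESeq2 test and 1211 with the coefficient of variation set at 10%, where the call for Adgre1 also ended.

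At rest, hMPDM differed from BMDM by higher interferon-stimulated and cholesterol synthesis genes and lower neutrophil genes. Of the 12461 genes 2371 were higher and 2395 lower, of which 165 and 344 by more than 2-fold. Of 43 interferon-stimulated genes 38 were higher and 0 lower, also adjusted over the list alone (median 1.39; camera adjusted p = 3.53e-27; adjusted p = 0.313 with an estimated correlation). Usp18, a brake on interferon signalling (ENSMUSG00000030107.9, chromosome 6, 121245906 to 121270916, mm10), stood at 59.1 CPM against 4.92 ± 0.105 CPM in BMDM (SD, n = 2; log2 3.58, SE 0.0986). Ifit3 (3.74), its near copy Ifit3b (3.81), the interferon regulatory factor gene Irf7 (3.21) and Ifit1 (2.99) were higher too, and reads shared between Ifit3 and Ifit3b are not excluded. All 21 cholesterol synthesis genes were higher, also adjusted over the list alone (median 0.94; camera adjusted p = 1.05e-20; adjusted p = 0.313 with an estimated correlation), with Tm7sf2 at 1.54, Idi1 at 1.46, Mvd at 1.40 and Insig1 at 1.29 (ENSMUSG00000045294.10, chromosome 5, 28071363 to 28078662, mm10). The fatty acid desaturase gene Scd1 was higher by 3.44 (SE 0.0671) and the ceruloplasmin gene Cp by 4.04. Stress genes were higher in 4 of 9 and lower in 0 (5 adjusted over the list alone; median 0.20; camera adjusted p = 0.0137; adjusted p = 0.313 with an estimated correlation).

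Mecom, a haematopoietic transcription factor gene (ENSMUSG00000027684.12, chromosome 3, 29951296 to 30548008, mm10), was not counted in BMDM or RAW and stood at 6.73 CPM in unstimulated hMPDM, at least 83.8-fold higher than BMDM. Klhl4 was at least 63.6-fold higher and Cyp2s1 had a ratio of 317 (108 to 1542). Of 20 tested progenitor genes 11 were higher and 2, Meis1 (-1.08) and Cd48 (-0.70), lower, also adjusted over the list alone (median 0.60; camera adjusted p = 0.00588; adjusted p = 0.313 with an estimated correlation). Ms4a3 (2.74), Hoxb4 (1.93), Hoxa9 (1.86) and Hoxa7 (4.87 against 1.71 CPM) were higher. Of 12 tested neutrophil genes 9 were lower and 1, Csf3r (0.33), higher, also adjusted over the list alone (median -1.58; camera adjusted p = 0.000133; adjusted p = 0.313 with an estimated correlation). Summed over the list, neutrophil genes made up 155 and 159.9 CPM by library size in the BMDM libraries at rest and 80.2 CPM in hMPDM. Ltf (-3.84), Ngp (-3.21) and S100a9 (-2.22), which encode granule or calcium-binding proteins, were lower, and Cebpe had 1 count in hMPDM, a ratio of 9.80 (1.58 to 404).

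Of 24 immediate early genes 15 were lower in hMPDM and 1, Jun (0.27), higher, also adjusted over the list alone (median -0.46; camera adjusted p = 0.00101; adjusted p = 0.313 with an estimated correlation), with Fosb at -3.22, Egr3 at -1.74 and Egr1 at -1.44. Fosl1 had 1 count in hMPDM, a ratio of 13.8 (2.30 to 563). Of 18 glycolysis genes 10 were lower and 0 higher (11 and 1 adjusted over the list alone; median -0.26; camera adjusted p = 3.28e-05; adjusted p = 0.313 with an estimated correlation), with Slc16a3 at -1.47, Pfkfb3 at -1.19, Slc2a1 at 39.7 against 79.4 CPM, and Aldoa at -0.49. Lipo3 was at least 68.9-fold, Sema3c at least 28.9-fold and Ube2e2 at least 27.6-fold lower in hMPDM, and Tceal8 was lower by -6.33. Sel1l3 had a ratio of 289 (98.6 to 1401), Gdf3 of 132 (36.5 to 1096), Plpp3 of 136 (24.2 to 5381) and Ly86 of 114 (38.8 to 553). Cd14 (-1.25), Tnf (-0.60), Mki67 (-0.56) and Nfkbia (-0.30) were lower, and Tlr4 (0.54) and Csf1r (0.23) higher. Il1b (log2 -0.07, adjusted p = 0.894) and Adgre1 (0.07, adjusted p = 0.169) did not pass. With both states averaged, or a BMDM library left out, the calls for Egr3, Cebpe or Hoxa9 ended. Those for Egr3 and Cebpe also ended with the replicate block, and those for Egr3, Cebpe, Fosl1, Idi1 and Hoxa7 with the DESeq2 test. With thinned reads the calls for Nfkbia and Egr1 ended as well, the Csf1r, Nfkbia and Egr3 calls ended with the coefficient of variation set at 10%, and 1714 genes passed with the coefficient of variation set at 10%.

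At rest, RAW lacked or held little of many genes of differentiated macrophages and expressed genes not seen in BMDM. Of the 12461 genes 3381 were higher and 3901 lower, of which 713 and 1110 by more than 2-fold. Mrc1, the mannose receptor gene (ENSMUSG00000026712.3, chromosome 2, 14229392 to 14332057, mm10), stood at 92.1 CPM against 2070.5 ± 20.2 CPM in BMDM (SD, n = 2; log2 -4.49, SE 0.0709). C1qb (ENSMUSG00000036905.8, chromosome 4, 136880129 to 136886187, mm10) stood at 5.49 CPM, from 21 counts, against 819.6 ± 5.44 CPM (log2 -7.22). Of 24 complement, lipid handling and lysosome genes 17 were lower and 3, Abcg1 (1.66), Nr1h3 (1.54) and Ctsz (0.27), higher, also adjusted over the list alone (median -0.92; camera adjusted p = 1.91e-09; adjusted p = 0.417 with an estimated correlation), with C1qc at -6.13, Apoe at -5.84 and C1qa at -4.55. Of 16 MHC class II and costimulation genes 12 were lower (13 adjusted over the list alone) and 1, Ctss (1.19), higher, with a median of -4.04 (-1.81 with genes at 0 set to their bound; camera adjusted p = 0.00324; adjusted p = 0.417 with an estimated correlation). H2-DMb1 was at least 28.2-fold lower, Ciita at least 3.41-fold and H2-Ob at least 1.57-fold, and H2-Eb1 had a ratio of 101 (18.2 to 4008).

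Of 25 macrophage identity genes 15 were lower in RAW and 6 higher (15 and 7 adjusted over the list alone; median -0.51; camera adjusted p = 0.00116; adjusted p = 0.417 with an estimated correlation). Marco was at least 16.3-fold lower, and Cd5l (-3.72), Mertk (-2.32) and Adgre1 (-1.26) were lower, while Cx3cr1 (2.11), Siglec1 (1.53), Msr1 (0.84), Fcgr1 (0.57), Lyz2 (0.31) and Csf1r (0.29) were higher. Of 11 alternative activation genes 8 were lower and 0 higher, also adjusted over the list alone (median -4.49, or -2.37 with genes at 0 set to their bound; camera adjusted p = 2.39e-05; adjusted p = 0.417 with an estimated correlation), with Fn1 at least 24.9-fold, Chil3 at least 24.6-fold and Cd163 at least 2.59-fold lower. Not counted in RAW were Cgnl1 (at least 229-fold), Ppp1r3b (at least 101-fold), Tceal8 (at least 56.8-fold), Fcho1 (at least 42.0-fold), Cercam (at least 39.5-fold), Peli2 (at least 39.3-fold), Pde3b (at least 38.1-fold) and Egln3 (at least 36.3-fold lower).

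The proto-oncogene Mycn (ENSMUSG00000037169.10, chromosome 12, 12936096 to 12941914, mm10) stood at 396 CPM in RAW and 0.114 ± 0.0926 CPM in BMDM (log2 11.70). It had only 3 and 1 counts in the BMDM libraries, so the size of this fold is imprecise. Zfhx4 was at least 691-fold, Ifi202b at least 336-fold, Spink5 at least 316-fold, Myh14 at least 147-fold and Trpm1 at least 134-fold higher, and Sgsm1 had a ratio of 1779 (315 to 70665). Eno1b had a ratio of 1212 (214 to 48267), with reads shared with Eno1 not excluded. Of 43 cell cycle genes 33 were higher and 3, E2f1 (-0.49), Pcna (-0.45) and Cenpa (-0.25), lower, also adjusted over the list alone (median 0.47; camera adjusted p = 2.81e-06; adjusted p = 0.417 with an estimated correlation), with Ccne1 at 1.44, Bub1 at 1.00, Rrm2 at 0.98 and Cdc6 at 0.94. Of 10 osteoclast genes 6 were higher and 3 lower, also adjusted over the list alone, and the list did not pass as a set (median 0.34; camera adjusted p = 0.282). Ctsk (5.25), Dcstamp (4.07) and Acp5 (3.14) were higher and Itgb3 lower (-7.06). Nfkbia (0.53) and Cd14 (0.37) were higher and Tnfaip3 (-0.86) lower, and with both states averaged Nfkbia and Cd14 turned direction. Ptgs2 was higher (1.35, adjusted p = 0.0286), and its call ended without BMDM unstimulated replicate 1 and with thinned reads. The calls for H2-Ob and Cd163 ended with the DESeq2 test, and those for Cd14, Csf1r and Mki67 with the coefficient of variation set at 10%.

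Along chromosome 3, RAW expression was raised over a stretch from 84666192 to 130709444 (mm10), chosen after the values were seen. Its 240 expressed genes had a median log2 difference from BMDM of 0.50 at rest and 0.46 after LPS, and of -0.01 between hMPDM and BMDM. The other 183 genes of the chromosome had medians of -0.01 at rest and -0.18 after LPS.

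**Figure D3:**
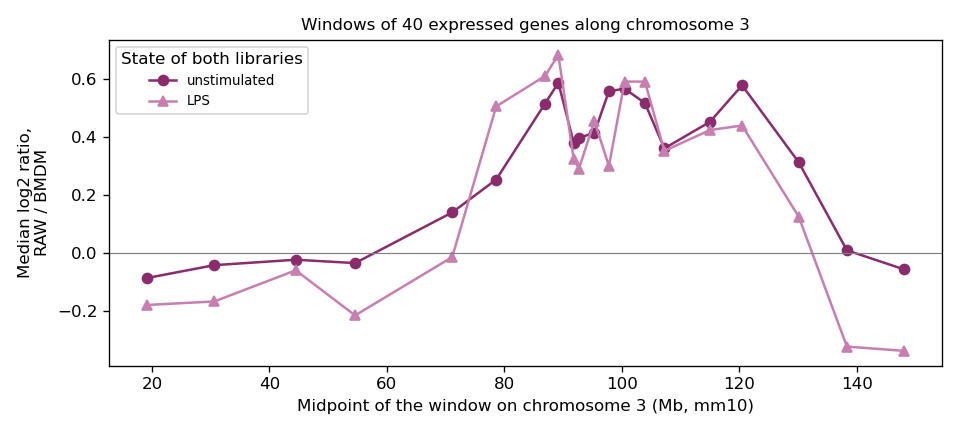
Median log2 ratio of RAW to BMDM in windows of 40 expressed genes along chromosome 3 (position in Mb, mm10), unstimulated and after LPS. The stretch from 84.7 to 130.71 Mb has a median of 0.50 at rest and 0.46 after LPS.

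Between hMPDM and RAW at rest, 532 genes were at least 4-fold higher in hMPDM and 354 in RAW by the size rule. Csf1, which encodes the macrophage growth factor CSF1, had 1 count in RAW and 290.6 CPM in hMPDM, a ratio of 1111 (199 to 43879), and Fcrls had a ratio of 1145 (205 to 45249). Eya1 had a ratio of 734 (132 to 29007) and Osbp2 was at least 139-fold higher in hMPDM. Interferon-stimulated genes passed upward in 17 of 43 and downward in 1, Ifi44 (median 1.86), with Oasl2 at 4.07, Ifit3 at 3.55 and Mx1 at 3.47. MHC class II genes passed upward in 6 of 16 (median 2.82, or 1.47 with genes at 0 set to their bound), and complement genes in 6 of 24 with 2 downward (median 1.04). Mrc1 was higher in hMPDM by 5.49, C1qb by 6.89 and the integrin gene Itgb3 by 6.36. RAW was higher for Mycn (-9.67), the histidine lyase gene Hal (-8.50) and Ctsk (-5.79). Flnc had 1 count in hMPDM, a ratio of 1611 (287 to 63788), and Slc9a4 was at least 295-fold and Zfhx4 at least 308-fold higher in RAW. With a minimum of 1 CPM in place of 5, 1456 genes passed.

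Relative to BMDM at rest, 622 genes were higher in both hMPDM and RAW, where independent lists would share 643, and 1270 were lower in both, where independent lists would share 750. Tceal8 was lower in both. A further 1447 differed in opposite directions, among them Cd14 and Mki67, which were lower in hMPDM and higher in RAW. Both comparisons use the same BMDM libraries, and 20 simulated data sets of unchanged groups set against them called at most 1 gene per comparison, so they do not bear on these overlaps. Across genes the 2 differences correlated at 0.127, against 0.171 in the simulations, with covariances of 0.244 and 0.0482.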

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

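The differences below are those in which the LPS response of 1 cell type departed from that of BMDM by a test of the difference itself. The comparisons were chosen before the data were examined, while the tests of explanations, other than the splits of the libraries, were chosen after seeing the data.

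For the common LPS response, 1 of the 34 splits of the 8 libraries into 4 against 4 that could be fitted, the real one, gave as many genes. The real split called 6121 genes and the highest other split 482. Many of the splits set both libraries of a cell type on the same side, and those balanced over the cell types as the real one is are too few for a share under 0.05.

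Between hMPDM and BMDM 979 genes differed in their LPS response, with adjusted p = 3.15e-54 for the interferon-stimulated list and 1.90e-05 for the complement and lipid handling list (camera, preset correlation; adjusted p = 0.439 for each with an estimated correlation). Smaller responses in hMPDM were found for Ifit1 (-3.06), Oasl1 (-2.86), Usp18 (-2.84), Ifit3 (-2.63), Ccl5 (-1.44), Cxcl10 (-0.65), Nfkbia (-0.38) and Tnfaip3 (-0.28). The call for Tnfaip3 ended with the DESeq2 test, with the replicate block and without either BMDM unstimulated library, and that for Cxcl10 without BMDM unstimulated replicate 2. With thinned reads the calls kept among the 22 genes named here were those for Ifit1, Oasl1, Usp18, Ifit3, Lpl and C3ar1, and with the coefficient of variation set at 10% those for Cxcl10, Nfkbia, Tnfaip3, Cd14, Adgre1, C3ar1, Abcg1, Apoe, Sema3c and Ube2e2 ended. Ifi208 (edgeR adjusted p = 0.000589) and Ifi213 (adjusted p = 0.00547) also rose less. Positive differences were found for Slc13a3 (4.12), Rasd2 (3.97, which fell in BMDM), Lpl (1.19), C3ar1 (0.78), Abcg1 (0.71), Apoe (0.70), Cd14 (0.37) and Adgre1 (0.19). The call for Adgre1 ended with the DESeq2 test, with the replicate block and without BMDM unstimulated replicate 1 or 2 or LPS replicate 1, and that for Apoe with the DESeq2 test and with the BMDM share taken out. Lipo3 (adjusted p = 0.00472), Sema3c (adjusted p = 0.0256), Ube2e2 (adjusted p = 0.0458) and Sel1l3 (adjusted p = 0.000716) had larger responses from 0 to 3 counts at rest. With the BMDM share taken out, Ube2e2 and Sel1l3 turned direction and the calls for Lipo3 and Sema3c ended.

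Interferon-stimulated genes were higher in unstimulated hMPDM than in BMDM, and their fold after LPS was smaller. Cells or reads of the LPS-treated hMPDM library carried over would need a share of 3.80% of that library, and 11 of 20 induced inflammatory genes lay below the level this would bring by more than counting error, so such carry-over alone is not in line with the values. A difference in library depth is not in line with them either, since 32 of 42 genes were still called higher with all libraries at the same depth. A higher resting level alone may account for the smaller fold, as the median of the 43 genes stood 1.38 above BMDM at rest and still 0.35 above it after LPS. The higher resting level itself may come from the cell type or from its culture, which 1 library per state does not separate.

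In the hMPDM LPS library, 16 genes near absent in unstimulated hMPDM stood at a pooled 10.8% of their BMDM LPS level. A candidate explanation is cells or reads of BMDM in the hMPDM LPS library. Of the 16, 2 genes, Gdf3 (1.46%) and Sel1l3 (5.603%), lay below that share by more than counting error (binomial p = 0.0595). The share was pooled from these same 16 genes, so this p-value cannot decide for or against the explanation. Choosing genes by a low value at rest brought no rise in RAW, where the share of the 256 genes chosen alike went to 0.894 times its value at rest. RAW is less like BMDM than hMPDM is, so this does not exclude some effect of the choice on the 16 genes. Among genes of at least 10 CPM in BMDM, 14 of 8533 lay below the 10.8% share in unstimulated hMPDM and 2 of 8347 in hMPDM after LPS. These counts do not bear on the explanation. The share was taken from the 16 genes in the same LPS library, and several of them are among the genes counted. That library is also shallower (5510319 against 15318338 counts), which by itself lowers the number below the share. Induction of these genes by LPS in hMPDM, or a mixed hMPDM culture, remains possible and was not tested.

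Between RAW and BMDM 2832 genes differed in their LPS response, with adjusted p = 1.81e-29 for the interferon-stimulated list, 2.34e-12 for the NF-kB list and 7.17e-09 for the cell cycle list (camera, preset correlation; adjusted p = 0.287, 0.287 and 0.411 with an estimated correlation). Smaller responses in RAW were found for Ccl5 (-7.65), Rsad2 (-7.39), Cmpk2 (-7.26), Cxcl10 (-7.24), Mx1 (-7.14), Ifit1 (-6.20), Socs3 (-3.53), Nfkbie (-2.91), Tnip3 (-2.79), Nfkbia (-2.10), Tnfaip3 (-2.004), Tnf (-1.90), Cd14 (-1.40), Adgre1 (-0.46) and Csf1r (-0.21). The sign for Csf1r turns when scaled by library size, and its call ended with the DESeq2 test, with thinned reads and, like that for Adgre1, with the coefficient of variation set at 10%. Positive differences were found for Myc (5.597), which fell in BMDM, and for cell cycle genes, which fell less in RAW: Cdc6 (1.86), Ccne2 (1.01), Kif20a (0.96) and Kif23 (0.95). Il12b (edgeR adjusted p = 0.000335), Slco3a1 (adjusted p = 0.00655), Nos2 (adjusted p = 0.00759), Plagl1 (adjusted p = 0.00899), Gem (adjusted p = 0.0107), Socs1 (adjusted p = 0.0131) and Cacnb3 (adjusted p = 0.0282) had smaller responses in RAW, with 0 to 3 counts in a RAW library. Bcl6b (adjusted p = 0.00222), Lcn2 (adjusted p = 0.0469) and Kcna3 (adjusted p = 0.0490) also had 0 to 3 counts in a RAW library, but their responses were larger in RAW. So was that of Ceacam19 (adjusted p = 0.0320), which was not counted in BMDM after LPS. The calls for Kcna3, Lcn2 and Ceacam19 ended when 1 BMDM library was left out, and those for Kcna3 and Lcn2 also with no filter. With thinned reads the calls for Bcl6b, Cacnb3 and Socs1 ended as well.

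Interferon-stimulated genes rose less in RAW than in BMDM. A difference in library depth is not in line with this, since 40 of 42 genes still rose less with all libraries at the same depth. Strain variants that lower the mapping of RAW reads would act alike at rest and after LPS, but the median over genes of the change in the difference from BMDM was -4.49. A weaker response of all induced genes alike is not in line with the values: RAW showed 0.165 of the BMDM log2 rise for interferon-stimulated genes, 0.467 for NF-kB genes and 0.604 for inflammatory genes, a difference of -0.303 between the first 2 (-0.466 to -0.159, a 95% interval from resampling genes, which are not replicates). A weaker interferon response particular to this line is a candidate explanation. With 1 library per state and 1 time after LPS, it cannot be told apart from culture or timing. Ifnb1 stood at 1 count in RAW after LPS, and its difference from BMDM did not pass.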

How the results depend on the processing

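Alternatives were set before seeing the data, except thinned reads, the 10% coefficient of variation and the BMDM share taken out, which were chosen after seeing the data. With DESeq2 size factors, with no filter and with the replicate block, each count of genes stayed within 1.5 times its main value. The replicate numbers do not pair the libraries (correlation of deviations -0.0346), and the block, a cruder model, gave 7751 genes for the BMDM response and 4981 for the common response. Leaving out each BMDM library gave 6568 to 7520 genes for the BMDM response and 890.0 to 1092 for the hMPDM difference of responses. The DESeq2 test gave 4159 genes for the BMDM response, 1365 for hMPDM against BMDM, 4463 for RAW against BMDM, and 264 and 1374 for the differences of the hMPDM and RAW responses. A test against a fold change of 2 gave 1555, 509 and 1823 in the first 3 comparisons, fewer by construction. Thinned reads gave 4906, 1836 and 178 (hMPDM difference of responses), and 4059 for the common response, so depth limits these counts. With the coefficient of variation at 10% the BMDM response held 5161 genes, hMPDM against BMDM 1714, and the differences of responses 123 (hMPDM) and 1211 (RAW). A log2 ratio of at least 1 gave 1694 genes for hMPDM LPS, 373 for RAW LPS and 2205 for hMPDM against RAW, and a minimum of 1 CPM gave 165 for RAW LPS and 1456 for hMPDM against RAW. The correlation of BMDM and hMPDM responses was 0.914 with a prior count of 8, 0.9499 from 10 CPM, 0.929 for genes called in BMDM, 0.854 with the BMDM share taken out, and 0.857 and 0.872 without BMDM replicate 2 and 1. That of BMDM and RAW was 0.503, 0.583 and 0.521, and 0.408 and 0.419 without these replicates. That of hMPDM and RAW was 0.497, 0.586 and 0.519, and 0.404 with the share taken out. With an estimated inter-gene correlation 0 of 114 gene list tests passed in camera, with 4 at an unadjusted p under 0.05, against 52 with the preset value. That form has little power at 2 or 4 residual degrees of freedom. The interferon-stimulated list of the BMDM response, in which every tested gene rose, had an unadjusted camera p of 0.103 there. The losses therefore do not separate moved from unmoved lists.

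Of 2718 checks of named genes 2595 kept direction and call, 119 lost the call and 4 reversed. Genes that failed the filter or had no adjusted p-value in an alternative were not counted. With the DESeq2 test, 15 of the 22 named genes were checked in the hMPDM difference of responses and 26 of the 32 in the RAW one. For the rest that test gives no answer. Averaged over both states, the RAW difference from BMDM was -0.52 for Nfkbia and -0.33 for Cd14, since both rose less with LPS in RAW. With the BMDM share taken out, 2 genes turned in the LPS response hMPDM minus BMDM: Sel1l3 (-3.91) and Ube2e2 (-0.94). There 1087 genes passed, of which 909 were shared with the 979. The interferon-stimulated list then had 35 smaller responses (median -1.09). With thinned reads 16 of the 22 named calls in that comparison ended, and 7 of 32 in the RAW one. The cause of the other shifts was not tested.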

Other observations

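The gene groups described in the report were chosen after the list results were seen, and the other lists of the BMDM response and those called in the other comparisons are given here. In the BMDM response, 18 of 25 TLR4 signalling genes rose and 5 fell (median 0.39; camera adjusted p = 0.000998), as did 5 and 0 of 7 dendritic cell genes (median 1.43; adjusted p = 0.0370), 7 and 0 of 12 neutrophil genes (median 0.51; adjusted p = 0.0442) and 5 and 12 of 21 cholesterol synthesis genes (median -0.20; adjusted p = 0.0442). Complement and lipid handling genes rose in 17 of 24 and fell in 2 (median 0.22; adjusted p = 0.00273), a direction that turns when scaled by library size, which also takes the TLR4 list median close to 0. Each of these 5 list calls was lost with an estimated correlation, and that for cholesterol synthesis also with the replicate block (camera adjusted p = 0.0597). Lists that did not pass were immediate early genes (12 rose and 7 fell of 24; adjusted p = 0.215), macrophage identity (12 and 7 of 25; 0.453), alternative activation (4 and 3 of 11; 0.453), p53 targets (8 and 9 of 21; 0.751), progenitors (7 and 7 of 20; 0.751), osteoclast (3 and 3 of 10; 0.751) and stress genes (4 and 5 of 9; 0.751). Lists too small to test as sets were mast cell (2 rose and 1 fell of 4), B cell (0 and 2 of 4), T and NK cell (2 and 1 of 4), fibroblast (2 and 0 of 3), erythroid (1 and 1 of 2) and sex-linked (0 and 0 of 1).

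Cholesterol synthesis genes held up better after LPS outside BMDM. In the RAW difference of responses 13 of 21 were higher and 0 lower (median 0.49; camera adjusted p = 7.17e-09; adjusted p = 0.424 with an estimated correlation), and in the hMPDM difference 8 and 0 (median 0.18; adjusted p = 1.16e-05; adjusted p = 0.460 with an estimated correlation). In the RAW difference 12 of 27 inflammatory genes were lower and 1 higher (median -1.16; adjusted p = 0.000380; adjusted p = 0.411 with an estimated correlation), and 14 of 23 nitric oxide and oxidative defence genes were lower and 1 higher (median -0.86; adjusted p = 9.46e-08; adjusted p = 0.287 with an estimated correlation). At rest 25 of 43 cell cycle genes were lower in hMPDM than in BMDM and 1, Tyms, higher (median -0.22; adjusted p = 4.52e-07; adjusted p = 0.313 with an estimated correlation), and 8 of 12 neutrophil genes were lower in RAW and 1 higher (median -2.34; adjusted p = 0.0402; adjusted p = 0.417 with an estimated correlation).

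In the common response the lists called beside those of the report were nitric oxide and oxidative defence (20 rose and 0 fell of 23; median 2.01; camera adjusted p = 1.24e-10), MHC class II (10 and 0 of 16; 0.67; adjusted p = 4.28e-05), glycolysis (11 and 0 of 18; 0.34; adjusted p = 0.000311), TLR4 signalling (16 and 3 of 25; 0.32; adjusted p = 0.00236), immediate early genes (12 and 5 of 24; 0.50; adjusted p = 0.00884), neutrophil (6 and 0 of 12; 0.65; adjusted p = 0.0146), dendritic cell (5 and 0 of 7; 1.07; adjusted p = 0.0149) and complement (10 and 1 of 24; 0.21; adjusted p = 0.0305). The glycolysis, TLR4 and complement medians are smaller than the shifts that library-size scaling brings in BMDM (-0.37) and hMPDM (-0.39). In the RAW difference of responses that scaling brings a shift of 0.27, which would remove most of the TLR4 median given next. In the RAW difference of responses 11 of 25 TLR4 signalling genes were lower and 2 higher (median -0.36; adjusted p = 0.00133) and 7 of 18 glycolysis genes lower and 0 higher (median -0.18; adjusted p = 0.00695, a direction that turns when scaled by library size). At rest 10 of 23 nitric oxide and oxidative defence genes were lower in hMPDM than in BMDM and 4 higher (median -0.13; adjusted p = 0.00107). With an estimated correlation each of these calls was lost, with adjusted p = 0.327 to 0.573 (common response), 0.287 and 0.609 (RAW) and 0.313 (hMPDM).

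Pseudogenes made up 57 of the 713 genes higher in RAW than in BMDM by more than 2-fold (7.99%), 12 of the 1110 lower, and 246 of the 12461 tested. Xist was lower in RAW (log2 -7.22).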
